A study of Mus musculus with 8 samples.

How the data were processed

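Small RNA was sequenced from the left spinal cord of C57BL/6 mice. In 4 libraries, labelled bone cancer pain, mouse lung cancer cells of the LL/2 line had been placed in the marrow space of the left femur. In 4 libraries, labelled sham, that space had received saline. Nothing in the labels says that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical.

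RNA was extracted with TRIzol, per the labels' protocols. Those protocols describe rRNA removal, fragmentation and cDNA library kits, while the sample descriptions name small RNA; the size selection and adapter handling of the small RNA libraries are not given in the sources used here. The tools fastp, STAR, Bowtie and Salmon and the genome build mm10 are named, with no version or role, per the submitters' processing notes. The authors deposited 1 table of 1396 mature mouse miRNAs in CPM, reads scaled to the total of each library, rounded to 2 decimals. The deposited CPM values of a library sum to between 669252 and 701908, so the denominator also counts reads outside the listed miRNAs. Columns of samples that could not be mapped numbered 0.

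The value of 1 read was recovered for each library from the steps between low CPM values. With a tolerance of 0.0051 CPM, 100% of the values above 0 were whole reads in every library. In bone cancer pain 3 the step, 0.100 CPM, is close to 0.1, but 16.6% of its values of at least 1 CPM were multiples of 0.1 CPM within that tolerance, so its steps are not those of values rounded to 0.1 CPM. The reads assigned to listed miRNAs were 5672862, 8524384, 6672639 and 7826594 in bone cancer pain libraries 1 to 4 and 6572676, 9260169, 8666057 and 5220739 in sham libraries 1 to 4. The library totals behind the CPM ran from 7686762 to 13498956 reads. A floor of 3 reads corresponds to 0.222 to 0.390 CPM. The floor covers counting error only, since reads amplified by PCR are not independent molecules. Libraries of the same group differed by a chi-square per degree of freedom of 37.1 to 587, so none was a copy of another.

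The comparison, its filter, the lists, the settings to vary and the rule for naming miRNAs were fixed before the data were examined. The count at an unadjusted p under 0.05 alone and the permutation test of list means were added afterwards. miRNAs with a mean of at least 1 CPM over the 8 libraries were tested, which kept 605 and left out 791. Values were analysed as log2(CPM + 1) without rescaling, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change on this scale understates the change of miRNAs near 1 CPM. Intervals are 95% intervals of the log2 fold change, bone cancer pain minus sham, from the spread between libraries.

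miRNA lists of cell types, families and clusters, 14 in all, were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and a two-sided exact permutation test of the list mean over all 70 arrangements of the labels, whose smallest possible p is 0.0286. fry tests whether the members move one way on balance and does not compare a list with other miRNAs. List membership went by miRNA number, all arms and copies included, and some miRNAs are in more than 1 list.

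The text names miRNAs by a rule with 4 parts. It takes up to 15 higher and 15 lower past the adjusted threshold. With fewer than 10 past it, the rule takes the 10 higher and the 10 lower with the smallest unadjusted p, named as not past it. From each list it takes up to 4 members with the smallest unadjusted p. It adds the 5 most abundant. This gave 65 miRNAs, and any other is marked as chosen after its values were seen. All 65 were matched by name to miRNA genes of GENCODE M21 (GRCm38), with alternative names from the RefSeq table of the same assembly; a mature miRNA with several gene copies cannot be assigned to one of them. Among the tested names, 7 sets have identical values, miR-199a-3p and miR-199b-3p among them. Counts of miRNAs take each name separately. miR-486a-5p and miR-486b-5p, and let-7a-1-3p and let-7c-2-3p, differ by at most 0.319% in any library and are not separable.

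As alternatives chosen after seeing the data, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads. Other added settings were CPM rescaled to the sum of the listed miRNAs, covariates for skeletal muscle and erythroid miRNA scores, and a fit without sham 1 and sham 2. Planned settings covered the pseudocount, the filter, scaling, the trend, array weights, a replicate block and leaving out each library. The procedure was tested on simulated data for these 605 miRNAs with the observed means, depths and dispersions. With 20 miRNAs changed, limma recovered 5.0% of those changed 1.5-fold, 57.9% at 2-fold and 90.0% at 4-fold. With 200 changed, it recovered 35.5%, 77.1% and 97.0%. Each set mixed changes of 1.5-fold, 2-fold and 4-fold, so recovery at one size depends on the others. The simulated miRNAs varied independently of each other, while those of the lists are correlated here, so recovery in the real data may differ.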

Results

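The left spinal cord of mice with a tumour implanted in the left femur was compared with that of saline-injected sham mice, to screen for miRNAs that differ in bone cancer pain. Each group had 4 libraries. Between 978 and 1065 of the 1396 listed miRNAs were above 0 CPM in a library, and reads of listed miRNAs ranged from 5220739 to 9260169 per library. Means are given in CPM ± SD with n = 4 per group.

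The highest-ranked differences were in miR-143-3p and miR-145a-3p, abundant in smooth muscle and encoded side by side. miR-143-3p averaged 26947 ± 5187 CPM in bone cancer pain and 16607 ± 5315 in sham, a log2 fold change of 0.72 (95% interval 0.26 to 1.18). Its other arm, miR-143-5p, chosen after its values were seen, had a log2 fold change of 0.15 (95% interval -0.33 to 0.63). miR-145a-3p averaged 57.5 ± 7.11 against 39.7 ± 5.11 CPM, a log2 fold change of 0.53, with all 4 bone cancer pain libraries above every sham library. miR-329-5p and miR-341-3p, of the imprinted Dlk1-Dio3 cluster, ranked highest among the lower miRNAs, with 362 ± 44.1 against 472 ± 46.3 CPM and 266 ± 12.3 against 359 ± 72.5 CPM. None of these differences passed the adjusted threshold.

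With limma, 0 of the 605 miRNAs passed an adjusted p of 0.05, and the smallest adjusted p was 0.887. At an unadjusted p under 0.05 there were 28, 17 higher and 11 lower, where 30.25 are expected by chance. edgeR and DESeq2 on the recovered reads also called 0 after adjustment, with 43 and 31 at an unadjusted p under 0.05. A change of at least 2-fold at an unadjusted p under 0.05 was found for 0 miRNAs with limma, 4 with edgeR and 3 with DESeq2. The groups did not overlap for 22 miRNAs, 12 higher and 10 lower, where chance gives 2.86% of those tested, or 17.3. The 95% interval lay within 2-fold in both directions for 555 miRNAs (91.7%) and within 1.5-fold for 61.0%. These intervals are of CPM + 1 and hold for 1 miRNA at a time. They do not exclude larger changes in CPM of miRNAs near 1 CPM. Of the 184 miRNAs with a mean of at least 100 CPM, 169 (91.8%) had an interval within 2-fold. Leaving out 1 library moved the log2 fold change of 37 of the 65 miRNAs named in the text by over 1.5 times and turned 4 of them.

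The other 8 higher miRNAs with the smallest unadjusted p were miR-15a-5p, miR-17-5p, miR-23a-3p, miR-483-5p, miR-30b-5p, miR-669b-5p, miR-195a-5p and miR-142a-5p. miR-15a-5p and miR-195a-5p, which share a seed sequence, had log2 fold changes of 0.47 and 0.35. miR-142a-5p, a miRNA of blood-forming cells, averaged 105 ± 15.3 against 69.4 ± 25.7 CPM, a log2 fold change of 0.67, or 0.38 without sham 4. Its other arm, miR-142a-3p, chosen after its values were seen, had a log2 fold change of 0.13 (95% interval -0.59 to 0.84). miR-30b-5p averaged 288 ± 18.1 against 234 ± 22.3 CPM. miR-483-5p, within an intron of Igf2 (chromosome 7, 142654924 to 142654996, GRCm38), and miR-669b-5p, within an intron of Sfmbt2, were near the filter at 1.89 ± 0.924 and 2.23 ± 0.318 CPM in bone cancer pain.

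The other 8 lower miRNAs were miR-365-1-5p, miR-196a-2-3p, miR-299b-3p, miR-764-5p, miR-211-5p, miR-6239, miR-29c-5p and miR-331-3p. miR-196a-2-3p had the most negative log2 fold change of the 10 lower, -0.71 (95% interval -1.28 to -0.14), at 1.81 ± 0.942 against 3.42 ± 0.764 CPM. Without bone cancer pain 4 its log2 fold change was -0.47. The gene, Mir196a-2, lies in an intron of Hoxc5 on chromosome 15 (102973350 to 102973434). miR-196a-5p, chosen after its values were seen, is the other arm of Mir196a-2 and also comes from Mir196a-1. It had a log2 fold change of -0.15 (95% interval -0.74 to 0.45). miR-764-5p, in an intron of the serotonin receptor gene Htr2c on chromosome X, averaged 3.24 ± 0.616 against 4.87 ± 0.916 CPM, and miR-211-5p, in an intron of Trpm1 on chromosome 7, 16.3 ± 2.13 against 21.3 ± 0.954 CPM. For miR-365-1-5p the log2 fold change was -0.40 and for miR-6239 it was -0.48. miR-29c-5p averaged 45.5 ± 4.66 against 58.5 ± 8.07 CPM, and miR-331-3p 24.7 ± 2.79 against 35.2 ± 10.4 CPM.

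**Figure D1:**
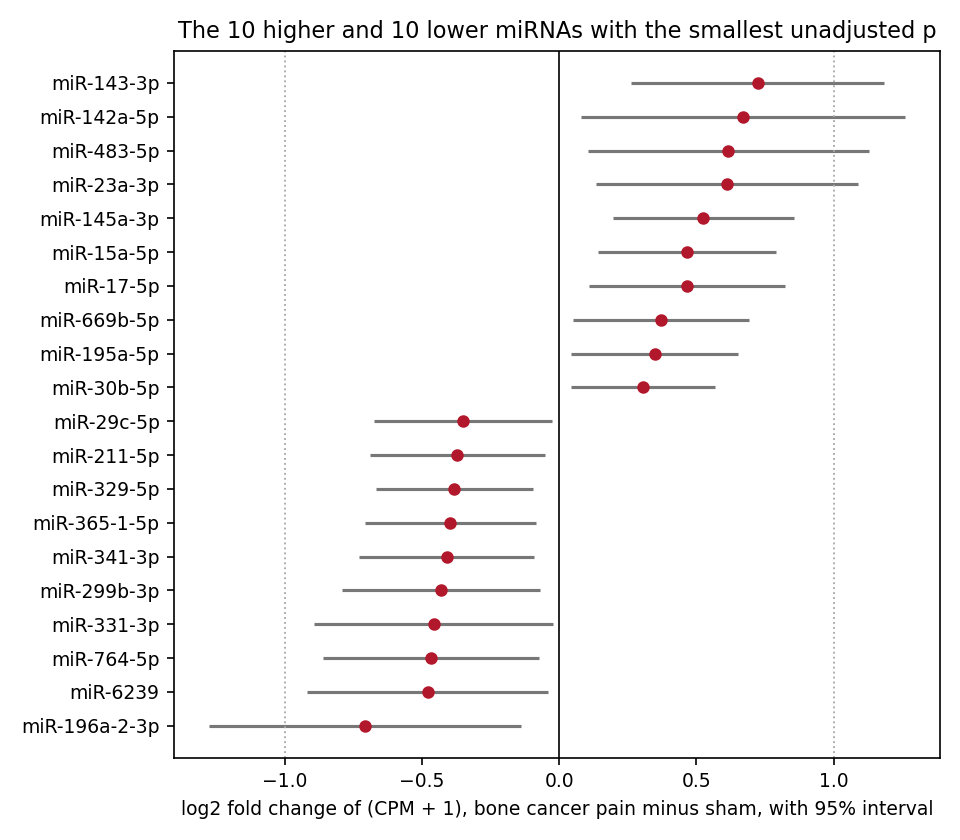
Points are log2 fold changes of (CPM + 1), bone cancer pain minus sham, and lines their 95% intervals from limma with 4 libraries per group, for the 10 higher and 10 lower miRNAs with the smallest unadjusted p; dotted lines mark 2-fold changes. Each interval leaves out 0, but no adjusted p was below 0.887.

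The vascular list, endothelial and smooth muscle miRNAs, was higher in bone cancer pain for 6 of its 6 measured members, with a median log2 fold change of 0.27. These members are both arms of miR-126a, miR-143 and miR-145a, so they are not independent, and their estimated correlation was 0.63. miR-143-3p and miR-145a-3p are encoded on the minus strand of chromosome 18, at 61649196 to 61649258 and 61647825 to 61647894, outside other annotated genes of that strand. Both passed with limma when adjusted over the list alone (2 of 6, smallest adjusted p 0.0164), against 0 of 6 over all tested. miR-126a-5p, an endothelial miRNA encoded within Egfl7 and miR-145a-5p had log2 fold changes of 0.26 (95% interval -0.03 to 0.54) and 0.29 (-0.10 to 0.68). By camera the list had an adjusted p of 0.000131 with the preset correlation and an adjusted p = 0.502 with an estimated correlation. The exact permutation p of its mean was 0.0857.

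The astrocyte-associated list, which shares 4 members with the vascular list, had 14 of 20 members higher and a median log2 fold change of 0.08. miR-23a-3p and miR-27a-3p, encoded side by side on chromosome 8, had log2 fold changes of 0.61 (95% interval 0.13 to 1.09) and 0.68 (0.04 to 1.33), and each was above every sham library in all 4 bone cancer pain libraries. Without bone cancer pain 4 these values were 0.40 and 0.34. In bone cancer pain 4 miR-27a-3p reached 2488 CPM. Its camera adjusted p was 0.0104, with an adjusted p = 0.513 with an estimated correlation and 0 of 20 members past limma adjusted over the list alone. The exact permutation p was 0.114. Without bone cancer pain 4 the camera adjusted p was 0.0629 and the median 0.0063, and without sham 1 and sham 2 they were 0.0636 and -0.021. The median was 0.056 without bone cancer pain 3, and 0.027, 0.053, 0.026 and 0.21 without sham 1, 2, 3 and 4.

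The miR-17-92 family, clusters tied to cell proliferation, was higher for 17 of 18 members, with a median log2 fold change of 0.21, or 0.32 without bone cancer pain 3. Some members are encoded together, so they are not independent, and their estimated correlation was 0.27. miR-17-5p averaged 48.3 ± 8.29 against 34.6 ± 4.57 CPM and miR-20a-5p 72.3 ± 6.81 against 54.7 ± 13.4 CPM. miR-17-3p and miR-19a-3p were near the filter, with log2 fold changes of 0.36 and 0.37. Mir17 (chromosome 14, 115043671 to 115043754), Mir19a and Mir20a lie in an exon of Mir17hg. By camera the adjusted p was 1.34e-05 with the preset correlation and the adjusted p = 0.502 with an estimated correlation, the exact permutation p of the list mean was 0.0571, and limma passed 0 of 18 adjusted over the list alone.

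Skeletal muscle miRNAs were lower in bone cancer pain for 7 of 7 members, with a median log2 fold change of -0.94, and differed strongly among libraries of 1 group. Both arms of miR-133a are among these members, so they are not independent, and their estimated correlation was 0.78. miR-133a-3p had a log2 fold change of -1.02 (95% interval -2.26 to 0.22) and miR-206-3p of -1.43 (-3.55 to 0.69). miR-133b-3p averaged 10.5 ± 6.02 against 22.8 ± 12.5 CPM and miR-133a-5p 3.05 ± 1.88 against 7.11 ± 5.28 CPM. In sham 1, sham 2 and bone cancer pain 4, miR-206-3p stood at 577, 410 and 296 CPM, and in sham 3 at 26.9 CPM. Of the other members, chosen after their values were seen, miR-208a-3p stood at 12.9 CPM in sham 1, at 0.09 CPM in bone cancer pain 4 and at 0 elsewhere, and miR-499-5p at 326 CPM in sham 1 and at most 19.04 CPM in any other library. The list name does not show that miR-208a-3p and miR-499-5p came from skeletal muscle, and their source in sham 1 was not tested. By camera the adjusted p was 0.000555 with the preset correlation and the adjusted p = 0.502 with an estimated correlation, the exact permutation p was 0.257, and limma passed 0 of 7 adjusted over the list alone. Without sham 3 the median was -1.45, without sham 1 it was -0.49 with a camera adjusted p of 0.168, and without sham 1 and sham 2 it was 0.084 with an adjusted p of 0.528.

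Erythroid miRNAs, a sign of blood in the tissue, had 5 of 6 members higher and a median log2 fold change of 0.49. That count takes miR-486a-5p and miR-486b-5p, which are not separable, as separate members. miR-451a averaged 994 ± 201 against 848 ± 788 CPM and stood at 2008 CPM in sham 3 and 285 CPM in sham 4. miR-144-5p and miR-144-3p, encoded beside it on chromosome 11, had log2 fold changes of 0.90 and 0.73, and miR-486a-3p, in an intron of Ank1, -0.22. The camera adjusted p was 0.0693, with an adjusted p = 0.792 with an estimated correlation and an exact permutation p of 0.343, and 0 of 6 members passed limma adjusted over the list alone. Without sham 3 the median was 0.91 and the camera adjusted p 2.32e-06, and without sham 2 and without bone cancer pain 3 the adjusted p was 0.0276 and 0.0300. It was 0.0381 with a filter of 10 CPM and 0.0383 with CPM rescaled to the listed miRNAs, while without sham 4 the median was 0.14 and the test pointed downward (adjusted p 0.961).

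**Figure D2:**
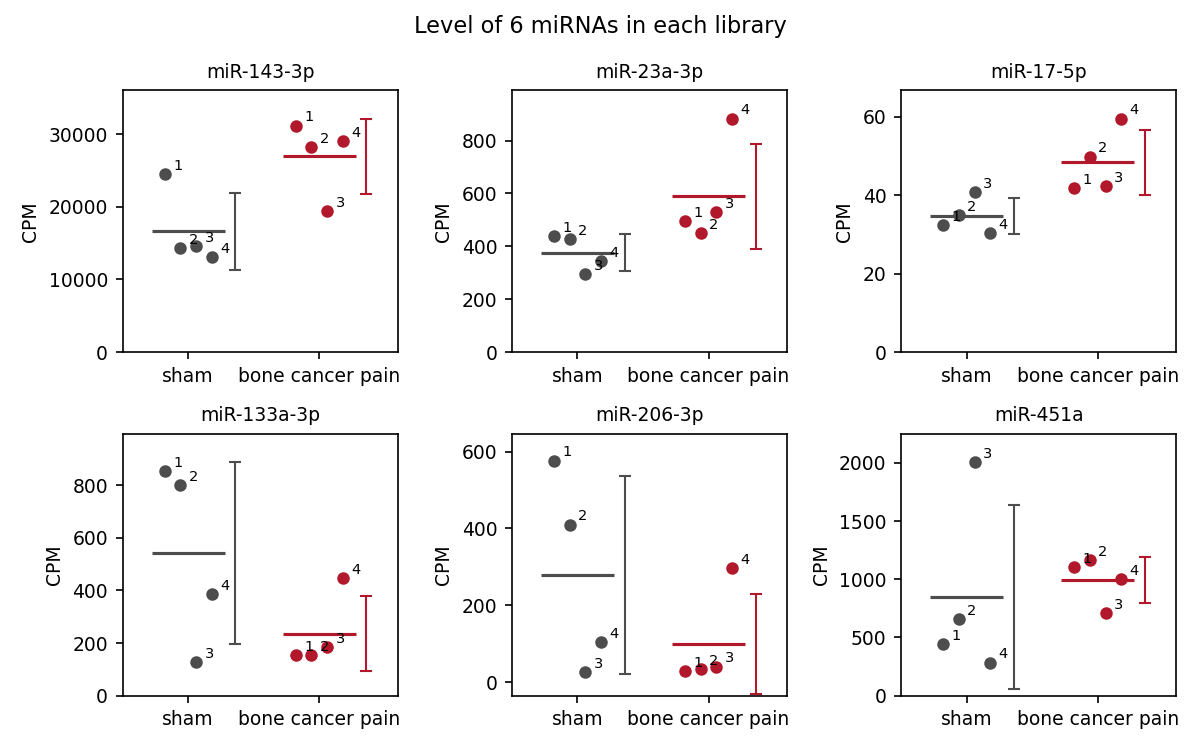
Points are CPM of 6 miRNAs in single libraries, numbered as labelled; horizontal lines are means of 4 libraries and vertical bars the mean ± SD, which reaches below 0 where the SD exceeds the mean. miR-206-3p ran from 26.9 to 577 CPM within the sham group, and miR-451a from 285 to 2008 CPM.

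In the Dlk1-Dio3 cluster, an imprinted and brain-enriched miRNA cluster of chromosome 12, 48 of 76 members were lower, with a median log2 fold change of -0.07. Besides miR-329-5p and miR-341-3p, miR-299b-3p averaged 3.80 ± 0.554 against 5.48 ± 0.962 CPM and miR-485-5p 99.2 ± 10.1 against 121 ± 12.2 CPM. The camera adjusted p was 0.00495, the adjusted p = 0.830 with an estimated correlation, the exact permutation p 0.486, and 0 of 76 passed limma adjusted over the list alone. Without bone cancer pain 4 the median was -0.023 and the camera adjusted p 0.414. The median was -0.044 without bone cancer pain 1, -0.15 without bone cancer pain 3, -0.12 without sham 2 and -0.011 without sham 4.

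Ciliated cell miRNAs, found in ependyma, were higher for 5 of 5 members, with a median log2 fold change of 0.21. miR-34c-5p averaged 1144 ± 93.5 against 993 ± 101 CPM, and miR-34b-5p, miR-34c-3p and miR-34b-3p had log2 fold changes of 0.29, 0.31 and 0.20. The camera adjusted p was 0.0163, the adjusted p = 0.502 with an estimated correlation and the exact permutation p 0.171, with 0 of 5 past limma adjusted over the list alone. The camera adjusted p was 0.0820 without bone cancer pain 3, 0.0629 without bone cancer pain 4, 0.119 without sham 1 and 0.256 without sham 1 and sham 2. It was 0.0904 without a filter, 0.0779 with array weights, and 0.171 and 0.164 with the muscle covariate and with both covariates.

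The remaining lists did not pass with camera at either correlation, and 0 of their members passed limma adjusted over the list alone. Neuron-enriched miRNAs were higher for 16 of 31 and lower for 15, with a median of 0.01 (camera adjusted p 0.856), and the test turned downward without bone cancer pain 3, sham 2 or sham 4 (medians -0.036, -0.023 and 0.092). miR-129-5p averaged 3621 ± 150 against 4229 ± 457 CPM, and miR-138-1-3p, miR-129-1-3p and miR-212-5p had log2 fold changes of 0.45, -0.27 and -0.24. The other arms miR-138-5p and miR-212-3p, chosen after their values were seen, had log2 fold changes of -0.10 and 0.25. Those of miR-138-2-3p and miR-129-2-3p, chosen likewise, were 0.41 and -0.25. Inflammation and myeloid miRNAs had a median of 0.04 with 9 of 14 higher (camera adjusted p 0.574). With muscle and erythroid covariates the adjusted p was 0.0369 at the preset correlation (adjusted p = 0.886 with an estimated correlation and no covariate), and without bone cancer pain 4 the median was -0.013. miR-155-5p averaged 18.7 ± 5.70 against 14.6 ± 0.801 CPM, and miR-150-3p and miR-146b-3p had log2 fold changes of -0.40 and -0.17. Both of these 3p arms were near the filter, at means of 1.13 and 1 CPM in bone cancer pain. Their other arms, miR-150-5p and miR-146b-5p, chosen after their values were seen, had log2 fold changes of 0.02 and 0.01. The sensory neuron cluster had 3 of 3 higher with a median of 0.19 (camera adjusted p 0.251), and miR-182-5p, miR-183-5p and miR-96-5p had log2 fold changes of 0.19, 0.20 and 0.11. Without sham 3 its camera adjusted p was 0.0454 at the preset correlation (adjusted p = 0.830 with an estimated correlation and all libraries), and without sham 4 its median was 0.0081, that of miR-96-5p was -0.062 and the test pointed downward.

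Oligodendrocyte miRNAs had 2 of 6 members higher, with a median of -0.05, a mean of 0.02 and a camera test pointing upward (adjusted p 0.906) that pointed downward under quantile normalization and without bone cancer pain 2 or sham 1 (medians 0.00066 and -0.14). miR-338-3p averaged 393 ± 51.9 against 324 ± 64.5 CPM and miR-219a-2-3p 1461 ± 57.5 against 1704 ± 523 CPM, with sham 4 at 2476 CPM and a log2 fold change of -0.18, or 0.016 without sham 4. miR-219a-5p and miR-219a-1-3p had log2 fold changes of 0.35 and -0.23, or 0.093 and -0.11 without bone cancer pain 4. The let-7 family had 11 of 20 higher (median 0.02, camera adjusted p 0.719), and the test turned downward without bone cancer pain 4 or sham 1 (medians -0.019 and -0.062). The arms let-7c-2-3p and let-7a-1-3p, which are not separable but count as separate members, had a log2 fold change of 0.31, let-7f-2-3p 0.28 and let-7c-1-3p 0.25. Their other arms, let-7c-5p, let-7a-5p and let-7f-5p, chosen after their values were seen, had log2 fold changes of -0.07, 0.07 and -0.06. The miR-29 and miR-30 families had 11 of 18 higher (median 0.03, or -0.00094 without bone cancer pain 3 and 0.079 without sham 4, camera adjusted p 0.524), with log2 fold changes of 0.32 for miR-29b-3p and 0.21 for miR-30d-3p.

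Of 57 miRNAs often studied in pain models, 35 were higher and 22 lower, with a median of 0.05 and a mean of -0.00; camera pointed upward with an adjusted p of 0.403. Without sham 1 the median was 0.0027 and without bone cancer pain 3 it was 0.0065. This list includes miR-329-5p, miR-483-5p and miR-195a-5p, given above, and miR-23b-3p, which averaged 1324 ± 254 against 1024 ± 164 CPM. It shares 3 members with the skeletal muscle list. Of the 14 lists, 6 passed an adjusted p of 0.05 by camera with the preset correlation, 0 with an estimated correlation, 0 by fry after adjustment and 0 by the exact permutation test after adjustment; before adjustment these last 3 also gave 0 under 0.05.

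**Figure D3:**
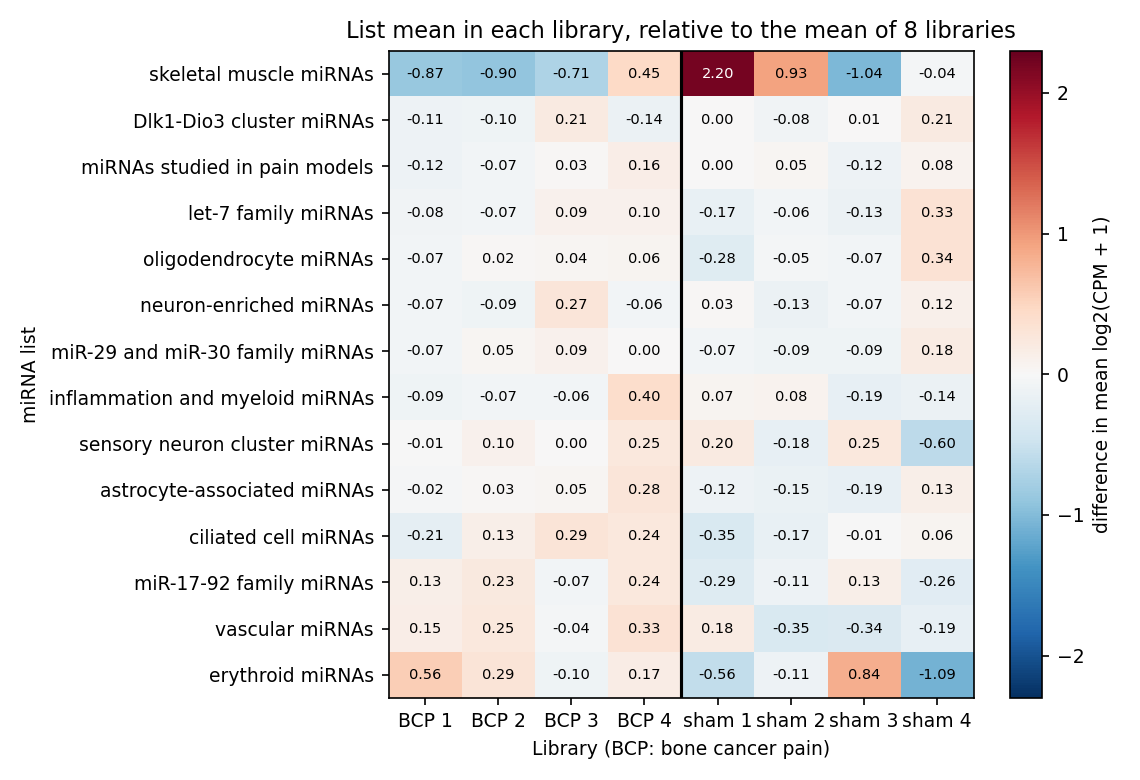
Each cell is the mean log2(CPM + 1) of a list in 1 library minus its mean over the 8 libraries, with lists ordered by the difference between groups and a line parting the bone cancer pain (BCP) from the sham libraries. Skeletal muscle miRNAs ran from -1.04 in sham 3 to 2.20 in sham 1.

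The most abundant miRNA was miR-10b-5p, encoded in the Hoxd cluster on chromosome 2 (74726070 to 74726137), at 107994 ± 15256 CPM in bone cancer pain and 112731 ± 8836 in sham, a log2 fold change of -0.07, or 0.015 without bone cancer pain 4. miR-9-5p, a neural miRNA with 3 gene copies, averaged 93645 ± 8119 against 93793 ± 3505 CPM, a log2 fold change of -0.01 that turned positive under median-of-ratios scaling and quantile normalization and without bone cancer pain 2, bone cancer pain 4 or sham 3. miR-127-3p, miR-26a-5p and miR-10a-5p were next by the mean over all 8 libraries, with 41297, 29821 and 26844 CPM in bone cancer pain. The 10 most abundant miRNAs held 40.8% ± 2.10 of all CPM in bone cancer pain and 39.8% ± 1.22 in sham, a difference of 1.08 points that was within the spread between libraries (two-sided exact permutation p 0.371, smallest possible 0.0286). The first 3 principal components of the log2 values held 32.3%, 25.7% and 14.9% of the variance, and their exact permutation p between groups was 0.914, 0.200 and 0.457. Their absolute correlation with the skeletal muscle score was 0.67, 0.70 and 0.25, and with the erythroid score 0.15, 0.95 and 0.05.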

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

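For the muscle, vascular and miR-17-92 patterns, the permutation tests of list means, the ratios, the connective tissue miRNAs, the erythroid covariate and the bounds used for scaling and blood were chosen only after the results or closely related values were seen. Both scalings, the fits without 1 library and the counts over other splits of the samples were set before.

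Single libraries stood far from the other 3 of their group in 10 of 166 groups of 4 values tested, where chance gives about 1 in 20, or 8.3. In bone cancer pain 4, miR-133b-3p (19.48 CPM), miR-133a-3p (447.87 CPM), miR-206-3p (295.83 CPM), the skeletal muscle list mean (6.05 on the log2 scale) and the inflammation and myeloid list mean (5.73) lay above the others. In bone cancer pain 3 the neuron-enriched list mean (6.62) and the Dlk1-Dio3 list mean (6.04) lay above the others, and in bone cancer pain 1 miR-764-5p (2.33 CPM) lay below. In sham 4, miR-341-3p (466.91 CPM) and the mean of the miR-29 and miR-30 families (7.72) lay above the others.

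Of the 35 splits of the 8 libraries into 4 and 4, 15 gave at least the 28 miRNAs of the real split at an unadjusted p under 0.05 (highest other 63), and 6 gave at least its 6 lists past camera with the preset correlation (highest other 7), so chance could not be excluded for these counts. For the counts with a real value of 0 the splits decide nothing, since all 35 give at least 0: the highest other was 6 past the adjusted threshold and 16 with a 2-fold change at an unadjusted p under 0.05. The split with 6 put bone cancer pain 1, 2 and 3 with sham 3. Their skeletal muscle list means were 4.57 to 4.90 and those of the other libraries 5.56 to 7.81, so this split parts the libraries by muscle miRNA level. The split with 16 put bone cancer pain 1 and 4 with sham 1 and 2, with muscle list means of 4.73, 6.05, 7.81 and 6.53. Whether the muscle miRNA level accounts for these counts was not tested.

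Skeletal muscle miRNAs were lower in bone cancer pain, with an exact permutation p of 0.257, so a chance uneven spread of libraries with much muscle miRNA stays open. Skeletal muscle carried along at dissection cannot be told apart. The check assumed that it would bring these miRNAs in near fixed proportions, and that assumption was not tested. The 4 most abundant members were miR-1a-3p, miR-133a-3p, miR-206-3p and miR-499-5p. For 4 of the 6 pairs among them the ratio varied less over the libraries than both levels. The ratio of miR-499-5p to miR-1a-3p ranged 14.2-fold, more than the 5.28-fold of miR-1a-3p but less than the 35.2-fold of miR-499-5p, which stood at 326 CPM in sham 1. Over all 6 members above 0 in every library it was 11 of 15 pairs, each of the other 4 with miR-499-5p. Sources of these miRNAs other than skeletal muscle were not tested. An effect of the tumour on muscle miRNAs was not tested separately from the group labels.

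Vascular miRNAs were higher in bone cancer pain, with an exact permutation p of 0.0857, so a chance difference between the libraries could account for it. Scaling of the libraries as the whole cause is argued against: the median log2 fold change, 0.27, was at least 0.26 under both other scalings, and kept at least 0.698 of its size in each fit without 1 library, the lowest without sham 4. More connective tissue cannot be told apart, because 4 connective tissue miRNAs chosen after related values were seen (miR-199a-5p, miR-199a-3p, miR-214-3p, miR-214-5p) had a median of 0.0032 with standard errors of 0.43 to 0.59. A response of vessels to the tumour remains open and untested.

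The miR-17-92 family was higher in bone cancer pain with an exact permutation p of 0.0571, which leaves chance open. More blood cannot be told apart. With the erythroid score as a covariate the median log2 fold change was 0.16, against 0.21 without it. With that covariate the median was 0.093 without bone cancer pain 4 and 0.10 without sham 1. The difference in list means was 0.27 without the covariate and 0.16 with it, with a 95% interval of -0.05 to 0.37 from a linear model. That interval holds both 0 and 0.27, so it does not decide the question. An effect of the tumour on these clusters remains open and untested.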

How the results depend on the processing

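Settings chosen after seeing the data were edgeR, DESeq2, CPM rescaled to the listed miRNAs, the covariates and the fit without sham 1 and sham 2. The count of miRNAs past the adjusted threshold was 0 under every setting run. No list test was run with DESeq2. Where a result below did not hold, the cause was not tested.

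The count at an unadjusted p under 0.05 was 28. It was 66 without a filter and 17 with a filter of 10 CPM, where other numbers of miRNAs were tested. It was 63 with array weights, 45 with muscle and erythroid covariates, 17 without sham 1 and sham 2 and 43 with edgeR. Leaving out 1 library gave 22 to 42. Of the 28, 24 kept that threshold and their direction under median-of-ratios scaling and 18 under quantile normalization. With edgeR 23 did so, with DESeq2 22 and with CPM rescaled to the listed miRNAs 26. The median-of-ratios factors ran from 0.956 in bone cancer pain 1 to 1.19 in sham 4. The count with at least a 2-fold change, 0, became 2 with a pseudocount of 0.1, 5 with array weights, 4 with edgeR and 3 with DESeq2. It was 1 with the muscle covariate, 1 with both covariates and 1 without sham 1 and sham 2. Leaving out 1 library gave 0 to 8, the 8 without sham 3 and 5 without bone cancer pain 4. The lists past camera, 6, were 3 without sham 1 and sham 2 and 3 to 8 when 1 library was left out, the 3 without bone cancer pain 4. The vascular and miR-17-92 lists passed in all 8 of those fits, with adjusted p up to 0.00396 and 0.00224 at the preset correlation, while each had an adjusted p = 0.502 with an estimated correlation and all libraries. Leaving out 1 library gave medians of 0.21 to 0.36 and 0.16 to 0.32.

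The difference in the top 10 share, 1.08 points, was -0.16 for the top 5 and 0.408 to 1.81 when 1 library was left out. miR-9-5p turned to 0.0040 with median-of-ratios scaling, 0.060 with quantile normalization, 0.00619 with edgeR and 0.00644 with DESeq2, and ran from -0.053 to 0.048 when 1 library was left out. Those ranges were -0.13 to 0.015 for miR-10b-5p, -0.27 to 0.016 for miR-219a-2-3p and -0.062 to 0.23 for miR-96-5p. miR-206-3p, part of the muscle covariate, turned to 0.17 with the muscle covariate, 0.18 with both covariates and 0.16 without sham 1 and sham 2, the last also turning miR-133a-5p to 0.093 and let-7f-2-3p to -0.026. miR-451a, part of the erythroid covariate, was -0.066 with both covariates.

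Median log2 fold changes follow of lists whose test turned direction, some of which keep the sign of their median. The skeletal muscle list was 0.036 with the muscle covariate, near 0 since that is built from it, and 0.084 without sham 1 and sham 2. The neuron-enriched list was 0.020 with array weights, -0.015 with a filter of 10 CPM and 0.0064 without a filter, and ran from -0.036 to 0.092 when 1 library was left out. The oligodendrocyte list was -0.049 without a filter, -0.063 with quantile normalization, -0.13 with the muscle covariate, -0.056 with both covariates and -0.19 without sham 1 and sham 2, with a range of -0.14 to 0.096. The erythroid list was -0.045 with both covariates, where a value near 0 follows since 1 of them is built from it (range 0.14 to 0.91), the inflammation and myeloid list 0.0084 with array weights (range -0.021 to 0.077) and the let-7 list -0.087 without sham 1 and sham 2 (range -0.062 to 0.14). The sensory neuron cluster ran from 0.0081 to 0.29.

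The replicate numbers showed no sign of pairing the samples, though this does not exclude a pairing: deviations of same-numbered libraries correlated, across miRNAs, at -0.06, -0.06, -0.01 and -0.31. With a replicate block 0 miRNAs passed, 21 had an unadjusted p under 0.05, 0 of them with a 2-fold change, 6 lists passed, and the top 10 share differed by 1.08 points, so the block changed no call. Depth limits mainly the miRNAs near 1 CPM, where 3 reads are 0.222 to 0.390 CPM.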

Other observations

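The miRNAs in this part outside the naming rule, and the settings with covariates, were chosen after seeing the data; what the covariate test below would have to show was set before it was run.

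Mir23a, Mir27a and Mir24-2 lie in a cluster on chromosome 8 (84208518 to 84208921, GRCm38). miR-23a-3p and miR-27a-3p had log2 fold changes of 0.61 (95% interval 0.13 to 1.09) and 0.68 (0.04 to 1.33), and miR-24-2-5p, from the same cluster, averaged 66.4 ± 11.1 CPM in bone cancer pain and 62.3 ± 8.31 in sham, a log2 fold change of 0.08 (95% interval -0.26 to 0.43). From the related cluster on chromosome 13, miR-23b-3p and miR-27b-3p had log2 fold changes of 0.37 and 0.21. None passed the adjusted threshold with limma, and the differences between cluster members were not tested.

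Among miRNAs encoded in the Hox clusters, miR-10b-5p ran from 100582 to 121637 CPM within the sham group and from 89970.5 to 122639 CPM within the bone cancer pain group. Within the bone cancer pain group miR-196a-5p stood at 261 CPM in bone cancer pain 3, with a group mean of 197 ± 65.8 CPM, and miR-196b-5p, encoded in Hoxa9, at 102 CPM in bone cancer pain 4. miR-499-5p, a muscle miRNA encoded in Myh7b, stood at 326 CPM in sham 1 and at 9.27 CPM in sham 3.

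One hypothesis was that uneven muscle and blood content widens the spread between libraries and hides changes, so that miRNAs might pass once both are accounted for. With muscle and erythroid scores as covariates, 0 miRNAs passed the adjusted threshold with limma, so what the hypothesis called for was not seen. At an unadjusted p under 0.05 there were 45 with limma, against 28 without covariates, a rise that was not tested. edgeR and DESeq2 were not run with covariates. The covariates use residual degrees of freedom in a fit of 8 libraries, and the scores come from the same libraries, so the count of 0 does not decide the question.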
